A study of Mus musculus with 5 samples.

How the data were processed

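ChIP-seq of whole adult mouse heart was represented by 3 region lists, 1 each for Tbx3, Nkx2-5 and Gata4, out of a series of 5 libraries. Samples were grouped by target from their labels, with 1 library per factor. The control library (the Tbx3 antibody in hearts without the TBX3 transgene) and the p300 library, which per the labels was sequenced on another platform (SOLiD), were not used here. Per the labels' protocols, the libraries of the 3 factors were made with an Illumina kit. The lists deposited by the authors hold a chromosome, a start and an end for each region and no score, height, fold, p-value or read number. The genome build is mm9 per the submitters' processing notes. The aligner, the peak caller, its threshold, any filter, the sequencing depth and the part played by the control library are not given in the sources used here. The values cannot therefore be weighted by depth or enrichment. A difference in length between lists cannot be separated from depth, antibody or threshold, nor, for Tbx3, from the TBX3 transgene. No region was narrower than 100 bp and no gap between neighbouring regions of a list was below 51 bp in the Tbx3 list or 52 bp in the other two, so sites closer than this cannot be told apart.

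The files were read as BED intervals, with starts counted from 0, and positions are printed counted from 1. The only gene table used here is RefSeq of GRCm38, another build. Of the Tbx3, Nkx2-5 and Gata4 regions, 116, 73 and 19 lie beyond the last gene of their chromosome in that table, most often on chromosome 7 for Tbx3 (77) and Nkx2-5 (49). No position was converted between builds. Beyond this check of the build, the table served only to count protein-coding gene symbols per chromosome (21887 in all, 966 of them on X). Comparisons of gene lists, of location in genes and of sequence motifs, which had been planned for the case of an mm9 annotation or genome, were not run. The test of region scores was not run either, because no score is given, and width took the place of the score in every ranking, as planned.

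Overlap of 2 lists was counted as the number of regions of the shorter list that overlap the longer one by at least 1 bp. It was compared with 1000 random placements of the shorter list, in which each region kept its chromosome and width and was placed within the span of all 3 lists on that chromosome. The one-sided empirical p was adjusted by the Benjamini-Hochberg method over the 3 pairs. The triple overlap was counted on the Gata4 list in the same way, and its dependence between lists was tested with Fisher's exact test within each list. The preference of Gata4 regions was tested with an exact McNemar test. Distances between centres of overlapping regions were compared with 1000 draws in which each pair kept its widths and its offset was random among those that overlap by at least 1 bp. Widths of shared and unshared regions were compared by a two-sided permutation test of the difference in medians with 100000 resamples. Groups were counted as regions with a neighbour of the same list within 10 kb and compared with random placements. Shares of a list carry exact Clopper-Pearson 95% intervals. Tests treat regions as units, which are not replicates: their p-values describe the lists and say nothing about variation between animals.

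The overlap count was tested on simulated data. Of each pair, 20 randomly placed shorter lists (6705 regions for Nkx2-5, 1756 for Gata4) had 200 regions replaced by ones set on regions of the longer list. The mean excess over random placement was 199 for Nkx2-5 in Tbx3, 200.1 for Gata4 in Tbx3 and 199.6 for Gata4 in Nkx2-5. With none planted it was -0.49, -1.02 and 0.088. The count equalled a direct comparison of all regions in each of the 20 lists of every setting. Of 40 randomly placed Nkx2-5 lists without planted overlaps, 1 gave an empirical p below 0.05 against the Tbx3 list. The simulated lists were placed by the same random model as the reference, and planted regions overlapped by construction. The simulation therefore checks the counting, and not whether this model suits lists whose regions are grouped.

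The tests of pairwise overlap, of the triple overlap with Fisher's test in the Gata4 list, of widths and of groups, the alternatives listed next and the rule for named regions were fixed before the data were examined. The McNemar test, Fisher's test in the Tbx3 and Nkx2-5 lists, the distances between centres with their random offsets, the overlap after fixed shifts, the regions per gene and the joined domains were chosen after the files had been seen. The rule names the 5 widest regions of each list, the 10 triple-overlap regions with the best mean width rank and the 3 best of each pair. Alternatives for the overlap were an overlap of at least 50% of the shorter region, centres within 500 bp, a distance of at most 1 kb, the wider 50% of each list, equal list sizes (the 1756 widest regions of each), regions resized to 500 bp, autosomes only, and a circular shift of the whole list along each chromosome. Gaps of 2 and 50 kb were tried for the groups. A local move of 2 to 10 kb as the random model, and the removal of mitochondrial, Y, chromosome-start (before 3.1 Mb) and very wide regions (400 bp or more, with neighbours within 10 kb), were added after seeing the data. The removal took out 447 Tbx3, 299 Nkx2-5 and 111 Gata4 regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.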

Results

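Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been applied to whole adult mouse heart (FVB/N background) with antibodies against 3 cardiac transcription factors and the coactivator p300. The series comprises 5 libraries, 1 for each target and 1 control. Tbx3 is a T-box repressor of the cardiac conduction system, Nkx2-5 is a homeodomain factor of cardiomyocytes and Gata4 is a zinc-finger factor of the developing and adult heart. Tbx3 was profiled in hearts carrying a TBX3 transgene (genotype Myh6-MCM;CAG-CAT-TBX3), and its control was the same antibody in Myh6-MCM hearts without it. Gata4, Nkx2-5 and p300 were profiled in wild-type hearts. Region lists of Tbx3, Nkx2-5 and Gata4 were analysed, and the control and p300 libraries were not analysed here. The question set by the design is where each factor occupies the heart genome and how far these places coincide. Each list comes from a single library, so the comparisons below describe these lists and have no replicate check. The Tbx3 list also differs from the Nkx2-5 and Gata4 lists in genotype, which cannot be separated from the factor. It describes hearts with the transgene and does not show where Tbx3 lies in wild-type hearts. Read depth and enrichment per region are unknown, since the files give positions only.

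Tbx3 had the most regions, 13242, followed by Nkx2-5 with 6705 and Gata4 with 1756. The regions were narrow in all 3 lists. Median width was 147 bp for Tbx3 (interquartile range 120 to 194 bp), 142 bp for Nkx2-5 (117 to 183 bp) and 149 bp for Gata4 (120 to 198 bp). Tbx3 regions covered 2.23 Mb of the genome, Nkx2-5 regions 1.08 Mb and Gata4 regions 0.309 Mb. No region was narrower than 100 bp. Regions of 400 bp or more were few: 176 for Tbx3, 56 for Nkx2-5 and 23 for Gata4.

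Chromosome 11 carried the largest number of Tbx3 and Nkx2-5 regions, 1080 (8.16%, exact 95% interval 7.70 to 8.64%) and 517 (7.71%, 7.08 to 8.38%). The X chromosome carried few regions in every list. It held 35 Tbx3 regions (0.264%, exact 95% interval 0.184 to 0.367%), 36 Nkx2-5 regions (0.537%, 0.376 to 0.743%) and 7 Gata4 regions (0.399%, 0.160 to 0.820%). These intervals cover counting error only. Relative to gene content in the GRCm38 gene table, X had 3.62 Tbx3 regions per 100 protein-coding genes, whereas the lowest autosome (chromosome 7) had 44.1 and the autosomal median was 63.8. The Nkx2-5 list had 3.73 on X against 23.2 on the lowest autosome and a median of 32.1, and the Gata4 list had 0.725 against 4.94 and a median of 8.84. The Y chromosome held 32 Nkx2-5 regions and no Tbx3 or Gata4 region. The mitochondrial genome held 16 Tbx3, 18 Nkx2-5 and 7 Gata4 regions.

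**Figure D1:**
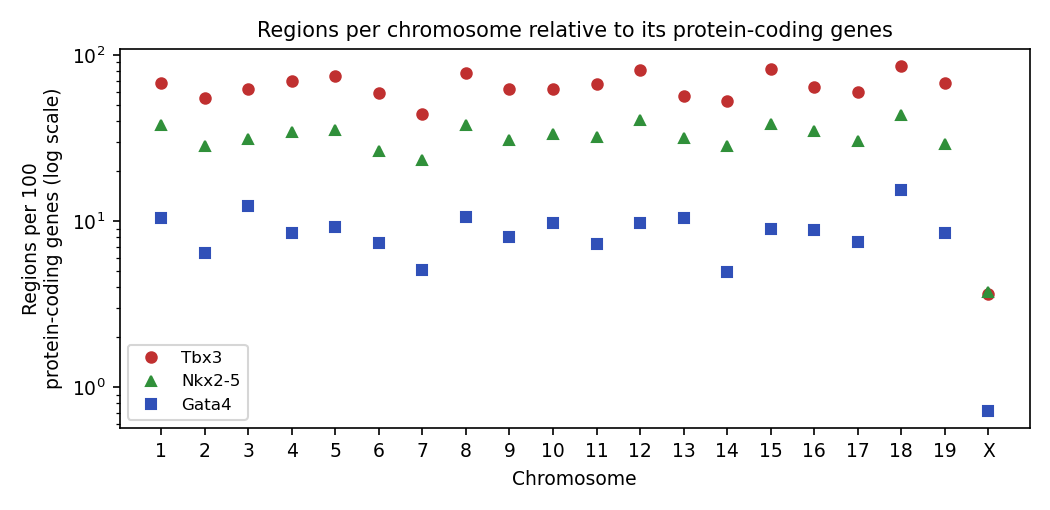
Regions per 100 protein-coding genes (log scale) on each autosome and X, for the Tbx3, Nkx2-5 and Gata4 lists, each point being 1 chromosome in 1 list. X lies below every autosome in all 3 lists, at 3.62 for Tbx3, 3.73 for Nkx2-5 and 0.725 for Gata4.

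Nkx2-5 and Tbx3, whose lists are the longest, shared more places than any other pair by number at full list lengths. With each list reduced to its 1756 widest regions the order turned, with 244 overlaps of Nkx2-5 in Tbx3 and 287 of Gata4 in Nkx2-5. That setting shortens the Nkx2-5 and Tbx3 lists but leaves the Gata4 list whole. Of the 6705 Nkx2-5 regions, 2403 (35.8%) overlapped a Tbx3 region by at least 1 bp, and 2423 of the 13242 Tbx3 regions (18.3%) overlapped an Nkx2-5 region. Random placement of the Nkx2-5 regions on their own chromosomes gave a mean of 24.9 overlaps and at most 39, so the observed number was 96.5-fold above random. The one-sided empirical p was 0.001, the smallest that 1000 placements can give, and was the same after Benjamini-Hochberg adjustment over the 3 pairs. The centres of overlapping Nkx2-5 and Tbx3 regions lay a median of 38 bp apart. With the offset of each pair drawn at random among all that overlap, the median was 84.5 bp on average and at least 79 bp over 1000 draws. The one-sided empirical p from these draws was 0.001, the smallest possible, and was the same after adjustment over the 3 pairs. The overlap was tied to position: after each Nkx2-5 region was moved by a random 2 to 10 kb, a mean of 73.1 and at most 99 still overlapped a Tbx3 region. Without the X, Y and mitochondrial chromosomes random overlap was rarer, and the excess was 193-fold, below the 354-fold of Gata4 in Nkx2-5.

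Gata4 regions coincided with Nkx2-5 regions more often than with Tbx3 regions, although the Tbx3 list is longer than the Nkx2-5 list. Of the 1756 Gata4 regions, 587 (33.4%) overlapped Nkx2-5 and 374 (21.3%) overlapped Tbx3. Against random placement these were excesses of 83.9-fold (mean 6.999, at most 13) and 42.4-fold (mean 8.82, at most 17), with one-sided empirical and adjusted p of 0.001 for both, again the smallest value possible. On autosomes only they were 354-fold and 116-fold, and against the moves of 2 to 10 kb they were 37.6-fold and 18.9-fold. Gata4 regions in the Nkx2-5 list alone numbered 382, against 169 in the Tbx3 list alone, a 2.26-fold difference (exact McNemar test, two-sided p = 5.8e-20). With each list reduced to its 1756 widest regions, the numbers were 245 and 42 (p = 5.0e-36, exact McNemar test). This setting keeps every Gata4 region but a smaller part of the Tbx3 list than of the Nkx2-5 list. The larger difference there cannot be told apart from this unequal cut. With the same share of each list kept, its wider regions, the numbers were 183 and 52 (p = 2.7e-18, exact McNemar test). Centres of overlapping regions lay a median of 44.5 bp apart for Gata4 and Nkx2-5, against 88.2 bp with random offsets, and 63 bp apart for Gata4 and Tbx3, against 84.9 bp. The empirical p from 1000 draws of the offsets was 0.001 for both, before and after adjustment. Regions, not animals, are the units of these tests.

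**Figure D2:**
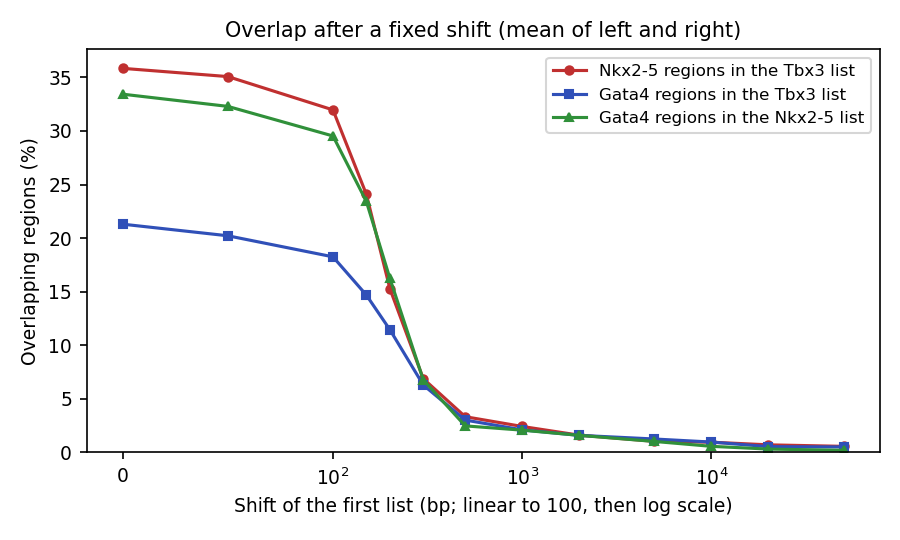
Share of regions of the first list that overlap the second list (%) after the first list is shifted by a fixed distance (bp; linear to 100 bp, log scale above), as the mean of a left and a right shift. Nkx2-5 regions in the Tbx3 list fall from 35.8% without a shift to 6.88% at 300 bp and 2.42% at 1000 bp, and the Gata4 curves fall over the same distances.

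A set of 205 Gata4 regions (11.7%, exact 95% interval 10.2 to 13.3%) overlapped both a Tbx3 and an Nkx2-5 region. Random placement gave a mean of 5.73 and at most 10, a 35.8-fold excess, which was 376-fold on autosomes only. The one-sided empirical p was 0.001, the smallest possible. Of these 205 regions, 201 were autosomal and 4 were mitochondrial. Among Gata4 regions, the Tbx3-overlapping ones also overlapped Nkx2-5 in 54.8% of cases, against 27.6% of the others (odds ratio 3.17, 95% interval 2.49 to 4.05; Fisher's exact test, two-sided p = 7.2e-22). Among Tbx3 regions, the Nkx2-5-overlapping ones also overlapped Gata4 in 9.12% of cases, against 1.53% of the others (odds ratio 6.44, 5.21 to 7.97; Fisher's exact test p = 2.1e-67). Among Nkx2-5 regions no such difference was detected. Gata4 overlapped 9.20% of those that also overlapped Tbx3 and 8.74% of those that did not (odds ratio 1.06, 0.884 to 1.26; Fisher's exact test p = 0.532). Counting regions within 1 kb of each other as shared raised this odds ratio to 1.20 (Fisher's exact test p = 0.0187).

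Regions that overlapped neither of the other lists by at least 1 bp numbered 10653 of the Tbx3 regions (80.4%), 3926 of the Nkx2-5 regions (58.6%) and 1000 of the Gata4 regions (56.9%). Counting regions within 1 kb of each other as shared left 73.6%, 50.2% and 48.6% in no other list, which for Gata4 is fewer regions than were shared. Nkx2-5 and Gata4 overlapped without Tbx3 at 376 Nkx2-5 regions, and Nkx2-5 and Tbx3 without Gata4 at 2182.

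**Figure D3:**
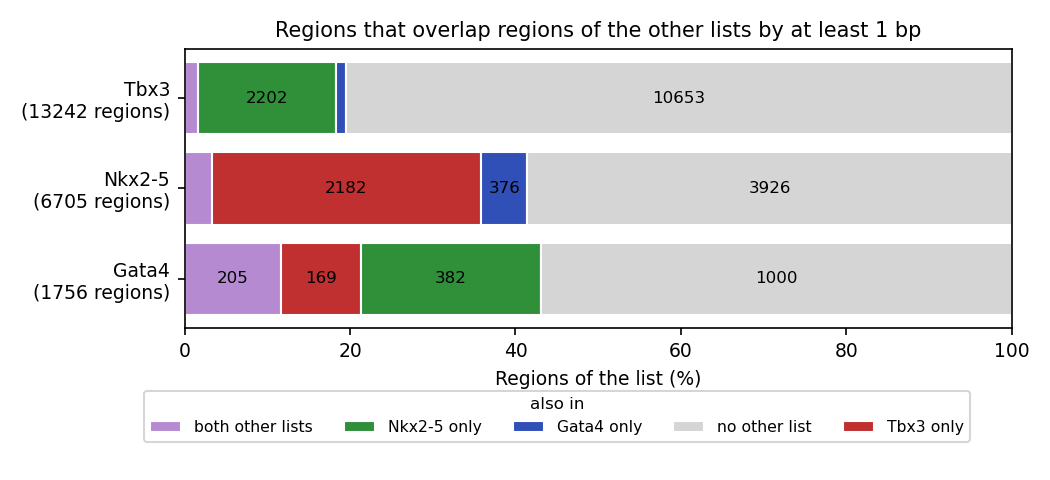
Share of the regions of each list (%) that overlap both other lists, 1 other list or none by at least 1 bp; numbers in the bars are regions. At the full list lengths, the part found in no other list is 80.4% for Tbx3, 58.6% for Nkx2-5 and 56.9% for Gata4.

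Regions shared with another list were wider than those that were not. Median width was 166 against 143 bp for Tbx3, 159 against 133 bp for Nkx2-5 and 162 against 142 bp for Gata4. Each two-sided permutation test gave p = 1e-05, the smallest that 100000 resamples can give, and the same value after adjustment over the 3 lists. In the widest quartile of Nkx2-5 regions 59.6% were shared, against 30.1% in the narrowest. The corresponding shares were 27.8% and 13.2% for Tbx3 and 57.0% and 35.4% for Gata4. A wider region also has more room to overlap by chance. Width gives no such room when regions with centres within 500 bp count as shared. Shared regions were then still wider, by 18 bp for Tbx3, 22 bp for Nkx2-5 and 19 bp for Gata4 (permutation test, p = 1e-05 for each). This argues against room to overlap as the whole source of the difference.

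The widest regions of the 3 lists fell on the same few loci. Of the 15 regions made up of the 5 widest of each list, 7 were on chromosome 17, 6 on the mitochondrial genome and 2 on chromosome 2. On chromosome 17 (mm9), Gata4 had a region of 3383 bp at 39979944 to 39983326, Tbx3 one of 3390 bp at 39979939 to 39983328, and Nkx2-5 adjoining regions of 1907 bp at 39979944 to 39981850 and 1834 bp at 39981903 to 39983736. A further block followed there at 39984383 to 39985770 for Gata4, 39984384 to 39985770 for Nkx2-5 and 39984454 to 39985782 for Tbx3. On the mitochondrial genome, Gata4 regions of 4806 bp at 3 to 4808 and 4074 bp at 11610 to 15683 contained Tbx3 regions at 2335 to 4318 and 12021 to 13486 and Nkx2-5 regions at 2963 to 3715 and 11838 to 13050. Tbx3 also had a mitochondrial region at 14150 to 15242. On chromosome 2, all 3 lists had a region within 98506395 to 98507466, and a region of each list started at 98502390. The 3 widest matches of each pair, 9 in all, were 6 on chromosome 17 and 3 on the mitochondrial genome, all at these loci.

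Of the 10 triple-overlap regions with the best mean width rank, 8 were likewise at these loci. The exceptions were chromosome 11 (mm9), with Gata4 at 108872991 to 108873357, Tbx3 at 108872963 to 108873435 and Nkx2-5 at 108872968 to 108873347, and chromosome 17, with Gata4 at 73371889 to 73372125, Tbx3 at 73371726 to 73372381 and Nkx2-5 at 73371802 to 73372416. Removal of the mitochondrial and Y regions, of regions before 3.1 Mb on any other chromosome and of regions within 10 kb of one of 400 bp or more left 172 of the 205 shared Gata4 regions. The best-ranked of these, chosen after their values were seen, was on chromosome 9, with Gata4 at 35112797 to 35113080, Tbx3 at 35112797 to 35113177 and Nkx2-5 at 35112803 to 35113111. The next were on chromosome 9 (Gata4 at 67011705 to 67011909), chromosome 12 (81237285 to 81237534) and chromosome 8 (129191918 to 129192142).

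Regions of the same factor gathered in groups. A Tbx3 neighbour lay within 10 kb of 6535 Tbx3 regions (49.4%), against 11.2% under random placement, a 4.40-fold excess. For Nkx2-5 the number was 2157 (32.2% against 6.07%, 5.30-fold) and for Gata4 298 (16.97% against 1.91%, 8.90-fold). The one-sided empirical p was 0.001 for each, the smallest that 1000 placements can give. Random placement is even along a chromosome, so any uneven spread, such as towards genes, adds to these excesses. Regions split from 1 stretch also count as a group: 3844 Tbx3, 1032 Nkx2-5 and 173 Gata4 regions had a neighbour within 2 kb. After the removal described above, 6166 Tbx3 (48.2%), 1930 Nkx2-5 (30.1%) and 219 Gata4 regions (13.3%) were still grouped. Joining the regions of all lists across gaps of 10 kb or less gave 12114 domains, of which 7270 held a single region, 2950 held regions of exactly 2 lists and 482 held regions of all 3. Of the 578 domains with 5 or more regions, 529 held both Tbx3 and Nkx2-5 regions and 221 held all 3 factors.

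The following domains were picked after the values were seen, by their number of regions (16 or more). The removal described above takes out 3 of them in full: the whole mitochondrial genome with 41 regions, chromosome 9 at 3018330 to 3036434 with 22 (7 Tbx3, 6 Nkx2-5, 9 Gata4) and the Y chromosome at 2856062 to 2899612 with 20, all of Nkx2-5. It takes out part of 3 others, as given with each. The autosomal domain with the most regions spanned 65.4 kb of chromosome 1 (mm9, 74034606 to 74100022) and held 19 Tbx3 regions, 8 Nkx2-5 regions and 1 Gata4 region, of which the removal takes out 4 Tbx3 regions and the Gata4 region. A domain on chromosome 2 (167651278 to 167692591) held 14 Tbx3, 10 Nkx2-5 and 1 Gata4 regions. On chromosome 9, the domain at 119378821 to 119410884 held 5 Tbx3, 10 Nkx2-5 and 3 Gata4 regions, 13 of these 18 taken out by the removal. On chromosome 4, the domain at 45470549 to 45502834 held 7 Tbx3, 6 Nkx2-5 and 3 Gata4 regions. On chromosome 5, the domain at 122951953 to 122977304 held 7 Tbx3, 7 Nkx2-5 and 2 Gata4 regions. Another domain on chromosome 4 (147337917 to 147374645) was made up mainly of Gata4 regions, with 12, beside 3 Nkx2-5 regions and 1 Tbx3 region, and the removal takes out 12 of its 16 regions, 11 of them Gata4. Genes at these positions are not named, since the gene table used here is of another build.

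**Figure D4:**
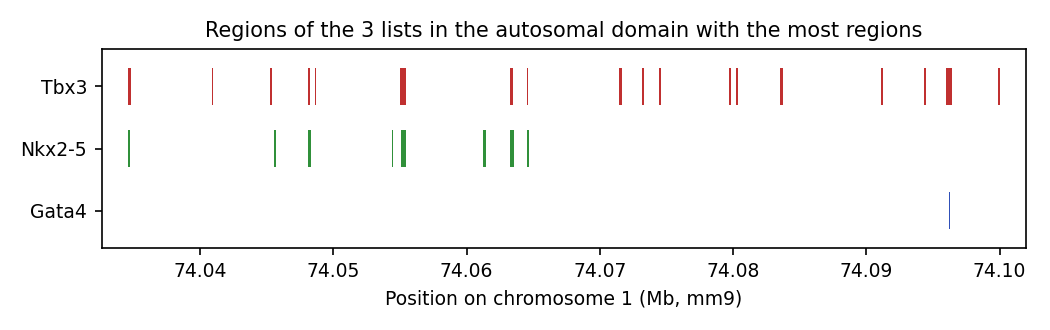
Regions of the Tbx3, Nkx2-5 and Gata4 lists (rows; each block is 1 region, drawn to scale) along chromosome 1 from 74034606 to 74100022 (Mb, mm9). The domain holds 19 Tbx3 regions, 8 Nkx2-5 regions and 1 Gata4 region.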

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

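The local move and the removal of mitochondrial, Y, chromosome-start and very wide regions were chosen after seeing the data, as was the test of the odds ratio in the Nkx2-5 list. All 49 alternatives of the excesses over random placement, for the 3 pairs, the triple overlap and the groups, kept their direction, each with an empirical p of 0.001. They ranged from 25.3-fold to 195-fold for Nkx2-5 in Tbx3, from 14.1-fold to 116-fold for Gata4 in Tbx3, from 37.6-fold to 382-fold for Gata4 in Nkx2-5 and from 8.42-fold to 378-fold for the triple overlap. Groups ranged from 1.80-fold to 11.2-fold for Tbx3, from 2.34-fold to 9.997-fold for Nkx2-5 and from 4.23-fold to 14.0-fold for Gata4. The highest overlap excesses came with autosomes only or without the mitochondrial and very wide regions, where random overlap is rare. The lowest overlap excesses came with equal list sizes, or for Gata4 in Nkx2-5 with the local move. Counts moved by more than 1.5 times where lists were shortened: the wider 50% of each list gave 988 overlaps of Nkx2-5 in Tbx3, 129 of Gata4 in Tbx3, 260 of Gata4 in Nkx2-5 and 77 triple overlaps. Equal list sizes gave 244, 84, 287 and 42, so Gata4 in Nkx2-5 then outnumbered Nkx2-5 in Tbx3. Regions found in no other list numbered 5572 for Tbx3, 2180 for Nkx2-5 and 566 for Gata4 in the wider 50%, and 1472 for Tbx3 and 1272 for Nkx2-5 at equal sizes. For Gata4 the number at equal sizes, 1427, stayed within 1.5 times, but its share rose from 56.9% to 81.3%. Counting regions within 1 kb as shared gave 310 triple overlaps. Gaps of 2 kb gave 3844 grouped Tbx3, 1032 Nkx2-5 and 173 Gata4 regions, and gaps of 50 kb gave 10429, 3973 and 563. The odds ratio in the Nkx2-5 list passed the threshold only with regions within 1 kb (1.20), while autosomes only gave 0.970 and removal of mitochondrial, Y, chromosome-start and very wide regions gave 0.925, neither past the threshold. The width differences kept their direction and call in all 6 alternatives. Comparisons of scores, gene lists, location in genes and motifs were not run. Leaving out replicates was not possible with 1 library per factor, and without depth the lengths of the lists cannot be set against each other.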

Other observations

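The removal of mitochondrial, Y, chromosome-start and very wide regions, the comparison of X with its genes, the use of Y regions for sex and the question of a control list were tests chosen only after the result was seen. The local move, the relation to gene density and the test of Tbx3 groups were added after the files were opened, before their own outcomes were known.

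Regions per Mb of an autosome rose with its protein-coding genes per Mb for Tbx3 and Nkx2-5. Across the 19 autosomes, Pearson's r was 0.79 for Tbx3 (permutation p = 5.0e-05, adjusted over 3 lists 7.5e-05; Spearman rho 0.73, p = 5.7e-04, adjusted 8.5e-04). For Nkx2-5 r was 0.83 (permutation p = 1e-05, the smallest possible, adjusted 3.0e-05; rho 0.84, p = 3.0e-05, adjusted 9.0e-05). For Gata4 the relation missed the threshold, with r = 0.45 (permutation p = 0.0561, adjusted 0.0561; rho 0.39, p = 0.104, adjusted 0.104). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.81, 0.81 and 0.45. The hypothesis that all 3 lists follow genes therefore stays undecided on its lowest r, 0.447. The prediction had counted a missed threshold in 1 list as evidence against it, but the r of that list is positive and the list has only 1756 regions, so this does not exclude a relation. Chromosomes are not replicates.

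A hypothesis that Tbx3 regions with a Tbx3 neighbour within 10 kb are shared with Nkx2-5 more than single ones was not settled. Of 6535 grouped Tbx3 regions, 18.9% overlapped Nkx2-5, against 17.7% of 6707 single ones (odds ratio 1.09, 95% interval 0.994 to 1.19; Fisher's exact test, two-sided p = 0.0653).

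The 205 Gata4 regions found in both other lists could reflect occupancy of the same short elements by the factors, which is a hypothesis, or technical sources. The lists come from separate libraries of whole heart, and Tbx3 from hearts with the TBX3 transgene. They therefore cannot show occupancy by several factors in the same cell or animal. Shared broad domains as the whole source are argued against: after random moves of 2 to 10 kb, at most 18 regions overlapped both lists in 1000 draws. Mitochondrial, Y, chromosome-start and very wide regions are argued against as the main source, since 172 of the 205 stayed without them. Narrower regions of technical origin elsewhere would pass this removal. Signal that each library gives whatever the antibody remains open, because the control library was not analysed here and no value in the lists decides. Loci such as the chromosome 17 block are where that explanation would be looked for first. Its outer borders in the Gata4 and Nkx2-5 lists were the same, 39979944 and 39985770. The mitochondrial genome is another such place, with 4 of the 205 regions. Tbx3, Nkx2-5 and Gata4 regions covered 8835, 7752 and 10909 bp of it. Shared borders also remain after the removal: in the best-ranked remaining match, on chromosome 9, the Gata4 and Tbx3 regions both start at 35112797.

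The X chromosome held fewer regions than its genes would give. A lower gene number is argued against: the regions per 100 protein-coding genes on X reached at most 16.1% of the lowest autosome in any list (Nkx2-5). A single X copy in males, with enrichment too weak to be listed, could lower the number and cannot be told apart from other sources here, since the labels used give no sex and the lists give no read counts. The 32 Y regions of the Nkx2-5 list, 20 of them between 2856062 and 2899612, do not settle the sex of these animals, and Y regions missing from the Tbx3 and Gata4 lists may come from sex, depth or threshold. Filtering of the X chromosome by the authors was not tested.

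Regions at the very start of chromosome 9, a place chosen after its values were seen, were dense in each list. Between 3000003 and 3036434 (mm9) there were 14 Gata4, 10 Nkx2-5 and 9 Tbx3 regions, although the Tbx3 list is the longest of the 3.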
